A study of Mus musculus with 3 samples.

How the data were processed

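ATAC-seq summit lists were analysed for 3 mouse mesenchymal stem cell libraries, 1 per group: day 0 before injury, day 7 immobilized and day 7 non-immobilized. Groups were taken from the sample labels. Libraries were made by the Omni-ATAC protocol, per the labels' protocols. The submitters' processing notes name FastQC, Trim Galore, cutadapt, Bowtie2 2.3.4.1, Picard, SAMtools 1.2, bedtools 2.28.0, MACS2 2.1.2, edgeR 3.26.5 and the genome build mm10, with no parameters or order. Whether reads were shifted for the transposase, which reads were filtered and what peak cutoff was used are not given in the sources used here.

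The deposited summit lists give, for each peak, a 1 bp summit and the authors' score, read here as the −log10 of a p or q value from the layout of MACS2 files; which of these it is was not stated. The score is the peak's own value and was used only to rank summits within a list. The authors called peaks separately in each library, as the deposited lists show. Lowest scores were 1.42, 1.78 and 1.33 and medians 10.9, 10.3 and 10.1 for day 0, day 7 immobilized and day 7 non-immobilized. The lists hold summits on 19 chromosomes, the autosomes, so X-linked genes were not measured. In the deposited run statistics, per the file headers, read numbers are counts, duplication is a fraction, and the alignment rate is a percent: 90.9%, 92.5% and 89.9% of reads aligned. Aligned pairs without duplicates were computed as the product of trimmed pairs, alignment rate and the share not duplicated. This is an upper estimate, since mitochondrial and multiply mapped reads were not known.

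Lists were reduced by score to the length of the shortest, 47912 summits, which left out 3810 summits at day 0 (7.37%) and 19492 at day 7 immobilized (28.9%). Each summit was widened by 250 bp on each side, and overlapping windows of the 3 libraries were merged. A region was called in a library if it held at least 1 of its summits. Absence from a list means that no summit passed, not that chromatin was closed. Each region was assigned to the protein-coding gene with the nearest end within 50 kb of its best-ranked summit. The gene table used, of assembly GRCm38.p6 (the assembly of mm10), gives gene starts and ends but no strand, exons or sequence. The nearest transcription start, planned before the data were examined, was therefore replaced by the nearest of either gene end, promoters by regions within 1 kb of either end, and exon, intron and motif analyses were not run. Positions count from 1.

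For each pair of libraries a, b and c denote the regions of a gene called only in the first, only in the second and in both, and values of a gene are given in that order. For each of 23 gene lists the share a/(a + b) was pooled over its genes and given a percentile among 10000 random lists, in which each gene was replaced by 1 with a similar number of regions. A list stood apart in the lowest or highest 2.5%. The mean of (a − b) per gene was ranked in the same way and is given where it fell on the other side of that threshold. The lists hold 469 genes, of which 460 lie on the autosomes; they cover osteogenic, chondrogenic, adipogenic, tenogenic, mesenchymal progenitor, matrix, focal adhesion, YAP/TAZ, BMP and TGF-beta, Wnt, inflammatory, AP-1, angiogenesis, cell cycle, limb position and housekeeping genes, and myeloid, lymphoid, endothelial, smooth muscle, skeletal muscle, Schwann and keratinocyte markers. Lists, groups, the main settings and the rule for named genes were fixed before the data were examined. The rule took, per pair and direction, the 10 genes with the largest (a − b) over the square root of (a + b), up to 4 members of each list by the same measure, and a fixed set of 18 genes. Krt5, Krt14 and Krt17, and Vwf in the comparison of the day 7 libraries, were named outside the rule, after their values were seen.

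Region building, gene distances and list percentiles were tested on simulated data. All 5000 simulated regions returned their pattern (100%). With one-library regions allotted at random, 5.0%, 5.0% and 6.0% of 200 lists of 20 genes stood apart in the pairs non-immobilized and immobilized, non-immobilized and day 0, and immobilized and day 0. With a true share of 75%, 50%, 50% and 80% of 10 lists did, so lists with differences of that size can be missed. Alternatives were lists as deposited, the 23956 best summits of each list (the stricter threshold), other widths and distances, distal regions alone and summits within 100 bp. After the data were seen, 4 more were added: regions among the 23956 best summits of one list and absent from the other's whole deposited list, assignment to the gene that holds the summit, lists without the member with the most one-library regions, and other window widths for the share of regions near a gene end. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.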

Results

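Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in mouse mesenchymal stem cells from a study of heterotopic ossification, the formation of bone outside the skeleton. One library came from cells taken before injury (day 0), 1 from cells labelled immobilized at day 7 after injury and 1 from cells labelled non-immobilized at day 7 after injury. With 1 library per group, no difference below has a replicate check, and no p-value is given. Intervals are exact (Clopper-Pearson) 95% binomial intervals that cover counting error only. The libraries held 176119937 read pairs at day 0, 143818952 at day 7 immobilized and 173029378 at day 7 non-immobilized. Duplicates made up 60.2%, 43.4% and 42.0%, which left an estimated 63640194, 75269683 and 90136518 aligned pairs. The deposited lists held 51722, 67404 and 47912 peak summits, so the library with the most pairs by this upper estimate had the shortest list. Each list was therefore reduced to its 47912 best-scoring summits. The lowest score kept was then 3.996 at day 0, 6.613 at day 7 immobilized and 1.328 at day 7 non-immobilized. Weaker summits of the immobilized list thus counted as absent, while the non-immobilized list was kept down to its lowest score.

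The 3 lists gave 67219 regions on chromosomes 1 to 19. Regions called in all 3 libraries numbered 29926, or 44.5% (44.1 to 44.9). Day 0 alone held 9556 regions, day 7 immobilized alone 8001 and day 7 non-immobilized alone 7110. The shared regions lay near gene ends more often: 35.3% (34.8 to 35.9) were within 1 kb of an end of a protein-coding gene. That share was 7.00% (6.50 to 7.53) of the regions called at day 0 alone, 7.29% (6.73 to 7.88) at day 7 immobilized alone and 10.8% (10.1 to 11.6) at day 7 non-immobilized alone. With summits widened by 500 bp these shares were 4.20%, 5.67% and 5.77%. The intervals of the day 7 libraries overlapped at that width (5.14 to 6.23 and 5.17 to 6.42), and both lay above that of day 0 (3.78 to 4.66). Shared regions also had better scores: their median rank at day 0 was 32.08%, where 0% is best, against 79.35% for day 0 alone. Rank was not matched. The share inside a gene was 54.79% for shared regions and 53.77%, 49.66% and 58.78% for day 0, day 7 immobilized and day 7 non-immobilized alone.

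**Figure D1:**
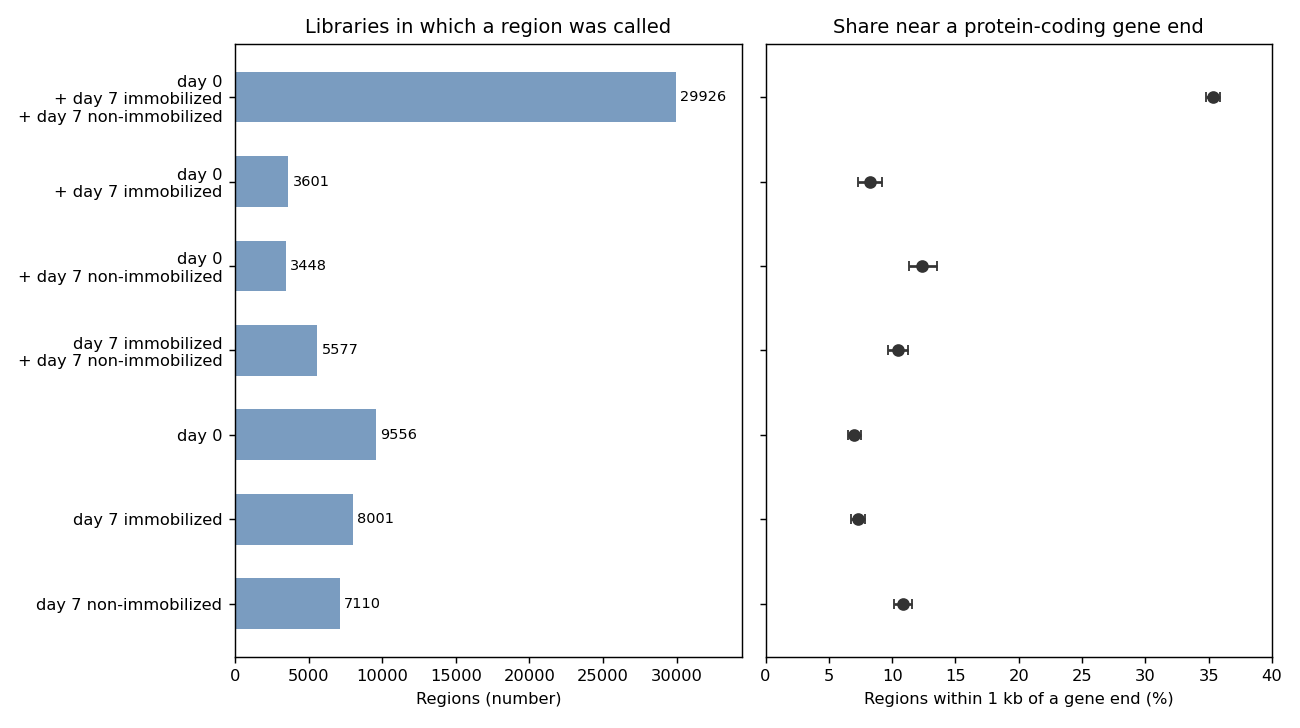
Left, bars give the number of regions called in each combination of the 3 libraries; right, points give the percent of those regions within 1 kb of a protein-coding gene end, with exact 95% binomial intervals (counting error only). The 29926 regions called in all 3 libraries have the highest share near a gene end, 35.3%.

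The first comparison asked how chromatin in these cells differed between the immobilized and the non-immobilized library at day 7 after injury. Regions near endothelial genes were called more often in the non-immobilized library, and regions near keratinocyte genes more often in the immobilized library. Over the 17 endothelial markers, 43 regions were called only in the non-immobilized library and 10 only in the immobilized one, a share of 81.1% that lay at percentile 99.99 of 10000 random lists of genes with similar numbers of regions. Over the 14 keratinocyte markers the counts were 2 and 29, a share of 6.45% at percentile 0.04. Lists that describe bone, cartilage, fat and tendon formation did not stand apart. In all, the day 7 libraries shared 35503 of 57663 regions (61.6%, 61.2 to 62.0), with 10558 called only in the non-immobilized and 11602 only in the immobilized library. Moving one list by 10 kb lowered the shared part to 2.81%.

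Of the 17 endothelial genes, 14 had more regions in the non-immobilized library, 1 (Vwf, von Willebrand factor) had more in the immobilized library, and 2 had equal numbers. Cdh5, which encodes the endothelial junction protein VE-cadherin (chromosome 8, 104101613 to 104144504, mm10), had 6 regions called only in the non-immobilized library, 0 only in the immobilized one and 4 in both. Pecam1, which encodes the endothelial surface protein CD31 (chromosome 11, 106654213 to 106715281), had 6, 1 and 6. Sox18, a transcription factor of vessel development, had 3, 0 and 1, and Egfl7 had 5, 1 and 3. The direction of the raw counts depended on list length: with the lists as deposited, 23 endothelial regions were called only in the non-immobilized and 30 only in the immobilized library, still at percentile 99.95 because random lists leaned further to the longer list. With only the 23956 best summits of each list the percentile was 97.0 for the endothelial and 9.11 for the keratinocyte list, and neither stood apart. Among regions from the 23956 best summits of one list that were absent from the other's whole deposited list, the 2 endothelial regions left were both in the non-immobilized library and the 5 keratinocyte regions all in the immobilized one, so the shares were at their limit and the percentiles (95.2 and 16.7) could not be more extreme.

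Of the 14 keratinocyte genes, 10 had more regions in the immobilized library, 0 had more in the non-immobilized one and 4 had equal numbers. Grhl3, a transcription factor of epidermal differentiation (chromosome 4, 135541887 to 135573632), had 7 regions called only in the immobilized library, 0 only in the non-immobilized one and 1 in both. Dsp, which encodes the desmosome protein desmoplakin, had 5 only in the immobilized library and 3 in both, Cdh1, which encodes E-cadherin, had 4 and 2, and Dsg3, which encodes a desmosomal cadherin, had 3 and 0. Krt14 had 3 regions, all in the immobilized library, and Krt5 had 1, also there only. The median rank of the 29 regions within the immobilized list was 81.1%, where 0% is the best score, against 77.5% for all 8265 regions within 50 kb of a gene end that were called in the immobilized and not the non-immobilized library, and 5 ranked in the better 50%. The 43 endothelial regions had a median rank of 68.3%, against 79.1% for all 7710 such regions of the non-immobilized library, and 7 ranked in the better 50%.

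**Figure D2:**
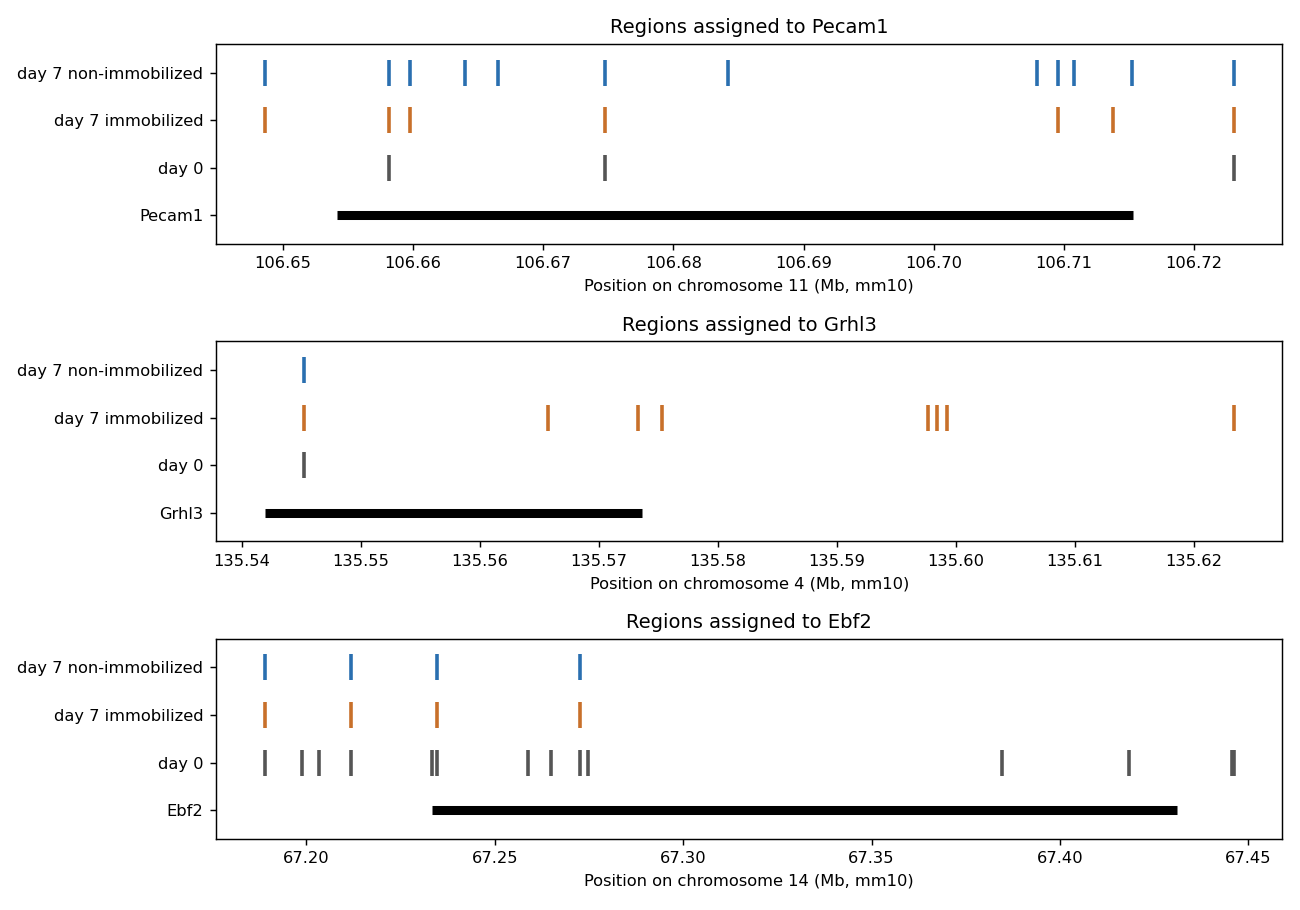
Vertical marks give the centres of regions assigned to Pecam1, Grhl3 and Ebf2 in each library, along the chromosome in Mb (mm10), and the black bar spans the gene. Pecam1 has 3 regions at day 0, 7 at day 7 immobilized and 12 at day 7 non-immobilized, Grhl3 has 1, 8 and 1, and Ebf2 has 14, 4 and 4.

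The lists for bone, cartilage, fat and tendon formation lay inside the range of random lists in this comparison, the tenogenic list near its edge. Osteogenic genes had 11 regions called only in the non-immobilized and 11 only in the immobilized library (percentile 62.5), chondrogenic genes 12 and 13 (47.0), adipogenic genes 17 and 22 (26.5) and tenogenic genes 19 and 9 (94.9). Runx2, the master regulator of osteoblasts (chromosome 17, 44495987 to 44814797), had 0 regions only in the non-immobilized library, 2 only in the immobilized one and 2 in both. Sox9, the corresponding regulator of cartilage (chromosome 11, 112782210 to 112787757), had 2, 0 and 2. Pparg, the main regulator of fat cells, had 4 regions, all in both libraries, while Cebpa had 1, 3 and 2 and Adipoq had 1 region in both. No region was assigned to the cartilage gene Acan in any library. Scx, a tendon transcription factor, had 0, 1 and 3, and Tppp3 had 2 regions, both shared. Fabp4, a fatty acid carrier of adipocytes, had 3, 0 and 1, and Acsl1 had 0, 4 and 3. With 1 library per group, the spread of such small counts between replicates is unknown.

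Lists of matrix and mechanical signalling genes also gave shares near those of random lists. Mesenchymal progenitor and fibroblast genes had 28 regions only in the non-immobilized and 25 only in the immobilized library (percentile 68.0), extracellular matrix genes 32 and 27 (66.2), focal adhesion and actin genes 30 and 27 (59.8), and genes of the YAP/TAZ pathway, which responds to mechanical load, 31 and 29 (55.8). Ddr2, a collagen receptor, had 0 regions only in the non-immobilized library, 2 only in the immobilized one and 6 in both. Yap1 had 1, 2 and 2, and its targets Ccn1, Ccn2 and Ankrd1 had 2, 2 and 5, then 0, 0 and 4, then 0, 0 and 2. Among matrix genes Col4a2 had 5, 0 and 11, Col6a3 had 7, 1 and 9, and Postn had 2 regions, both shared. Pdgfra had 2, 1 and 2 and Prrx1, a limb mesenchyme factor, had 3, 1 and 3. 

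The percentiles of the remaining lists in this comparison were 14.6 for BMP and TGF-beta signalling, 86.9 for Wnt signalling, 11.0 for the inflammatory response, 7.97 for AP-1 and immediate early factors, 82.3 for angiogenesis and hypoxia, 49.5 for the cell cycle, 76.4 for limb position and 35.4 for housekeeping genes. Among markers of other cell types they were 33.8 for myeloid, 46.1 for lymphoid, 85.2 for smooth muscle and pericyte, 47.2 for skeletal muscle and 24.7 for Schwann and nerve markers. Il1b, which encodes the cytokine interleukin 1 beta, had 6 regions only in the immobilized library and 0 elsewhere among the day 7 libraries, and Bach1, a transcription repressor that responds to heme, had 0, 6 and 9. Ptprc, the leukocyte marker CD45, had 1, 0 and 2.

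Ranked by the difference of the one-library counts over the square root of their sum, the genes that leaned most to the non-immobilized library were Spsb1 (10 against 0), Ago2 (7 against 0), Cdh5, Lrrc32 and Mgll (6 against 0 each), Chst15 and Bcr (8 against 1 each). Sfi1 and C130026I21Rik (8 against 0 each) and Zfp988 (6 against 0) belong to loci with near-identical copies, where read placement is uncertain. Neither the copies nor the read placement were measured here. With the lists as deposited the difference was -2 for Lrrc32, -4 for Mgll and -1 for Chst15, that is, towards the immobilized library. On the immobilized side stood Tekt5 (8 against 0), Grhl3 and Ppp1r14c (7 against 0 each), P3h2 (9 against 1), and Cwh43, Il1b, Myl10, Cers3, Perp and Ppp1r12a (6 against 0 each). Cers3, a ceramide synthase, and Perp, a desmosome component, are epidermal genes. Genes with 5 or more one-library regions that all fell in 1 library numbered 19 for the non-immobilized and 36 for the immobilized library. In 1000 random allotments the means were 9.01 and 12.95 and the highest values 20 and 24. Regions were allotted singly, so regions of 1 gene that tend to be called together were not allowed for.

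The second comparison set the non-immobilized day 7 library against day 0. Endothelial genes had 62 regions called only at day 7 and 13 only at day 0 (82.7%, percentile 100), and skeletal muscle markers 4 and 16 (20%, percentile 0.345). The 2 libraries shared 33374 of 59218 regions (56.4%, 56.0 to 56.8), with 12687 called only at day 7 and 13157 only at day 0. Of the 17 endothelial genes, 16 had more regions at day 7 and 1 had more at day 0. Pecam1 had 9 regions only at day 7, 0 only at day 0 and 3 in both, Sox18 had 4, 0 and 0, Robo4 3, 0 and 0, and Cdh5 9, 3 and 1. Among skeletal muscle genes, Pax7, the marker of muscle stem cells, had 0, 5 and 5, and Myod1 had 0, 3 and 3. The skeletal muscle list did not stand apart without its leading member (percentile 3.53), with the 23956 best summits of each list (29.4) or within 10 kb of a gene end (4.58). Among regions from the 23956 best summits of one list that were absent from the other's whole deposited list, endothelial genes had 19 at day 7 and 0 at day 0, a share at its limit, for which no percentile above 91.6 existed.

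Other lists lay inside the range of random lists, some close to its edge. Keratinocyte markers had 9 regions only in the non-immobilized day 7 library and 1 only at day 0 (percentile 97.4, but 99.6 for the mean difference per gene, which stands apart), and the YAP/TAZ list 40 and 20 (97.3). Smooth muscle and pericyte markers had 11 and 21 (3.80). Osteogenic genes had 10 and 18 (7.00), chondrogenic genes 14 and 17 (25.2), adipogenic genes 22 and 30 (11.1), tenogenic genes 20 and 18 (53.2) and mesenchymal progenitor genes 20 and 30 (5.28). Ebf2, a transcription factor of adipocyte progenitors (chromosome 14, 67233292 to 67430952), had 0 regions only at day 7, 10 only at day 0 and 4 in both. Dlk1, which encodes an inhibitor of adipogenesis, had 0, 6 and 3, and the insulin receptor substrate gene Irs2 had 1, 9 and 6. St3gal5 (9), Fam169b, Galnt16 and Abca8b (7 each), Rap1gap2, Colec12 and Mthfd1l (6 each) had 0 regions only at day 7 and the stated numbers only at day 0. On the day 7 side, Bcr had 8 against 0, N4bp1 and Xxylt1 10 against 1, Nr5a2 and Pdgfb, a growth factor for pericytes, 7 against 0, Ctif 9 against 1, and Kit, a receptor of stem and mast cells, 6 against 0. C130026I21Rik (9 against 0) and LOC115488016 (7 against 0) are uncertain because they may lie in repeated sequence, which was not measured. Runx2 had 0, 1 and 2, Sox9 had 1, 1 and 3, Pdgfra 0, 2 and 4, Prrx1 2, 4 and 4, and Ccn1 4, 0 and 3.

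The third comparison set the immobilized day 7 library against day 0. Keratinocyte genes had 35 regions called only at day 7 and 0 only at day 0 (100%, percentile 100), and AP-1 and immediate early genes 35 and 13 (72.9%, percentile 99.6). Smooth muscle and pericyte markers had 6 and 20 (23.1%, percentile 0.335), and limb position genes 12 and 25 (32.4%, percentile 2.1). The 2 libraries shared 33527 of 60109 regions (55.8%, 55.4 to 56.2), with 13578 called only at day 7 and 13004 only at day 0. Of the 14 keratinocyte genes, 11 had more regions at day 7 and 0 had more at day 0: Grhl3 had 7, 0 and 1, Dsp 6, 0 and 2, Cdh1 5, 0 and 1, and Dsg3 3, 0 and 0. Among AP-1 and immediate early genes, Bach1 had 9, 0 and 6, Fosl2 4, 0 and 4, Egr2 3, 0 and 2, and Fosb 2, 0 and 4. Rgs5, a pericyte marker, had 0, 4 and 1, and Abcc9 and Myh11 had 0, 3 and 2 each. None of the 4 lists stood apart with the 23956 best summits of each list, where keratinocyte markers lay at percentile 95.6, AP-1 genes at 90.1, smooth muscle markers at 6.40 and limb position genes at 29.6. The smooth muscle list lay at 5.35 within 10 kb, and the AP-1 list at 95.6 without its leading member, 38.4 within 10 kb and 89.5 with the lists as deposited. The limb list lay at 3.13 with the lists as deposited, 3.66 within 10 kb, 4.51 within 100 kb, 4.86 without its leading member and 16.7 with summits assigned to the gene that holds them. Among regions from the 23956 best summits of one list that were absent from the other's whole deposited list, AP-1 genes had 7 and 3 (percentile 47.4). Keratinocyte markers had 10 and 0 there, a share at its limit, for which no percentile above 81.2 existed, and limb position genes had 1 region, too few to give a side.

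In this comparison the endothelial list had 30 regions only at day 7 and 14 only at day 0 (percentile 94.3), the inflammatory list 44 and 23 (97.3) and the mesenchymal progenitor list 23 and 36 (2.74). By the mean difference per gene, the endothelial list (percentile 98.7) and the mesenchymal progenitor list (2.25) stood apart, and the inflammatory list (97.0) did not. Vwf had 6 regions only at day 7, 0 only at day 0 and 2 in both. Skeletal muscle markers had 7 and 17 (3.28). Osteogenic genes had 12 and 20 (6.95), chondrogenic genes 17 and 19 (33.5), adipogenic genes 31 and 34 (25.9) and tenogenic genes 10 and 18 (5.31). Ebf2 had 0, 10 and 4 here too. These are the same 10 regions as in the second comparison, counted in the single day 0 library, where they ranked from 56.61% to 97.95%. On the day 7 side, Ets2 had 11 against 0, Nedd9 11 against 1, Pkp1 8 against 0, P3h2 10 against 1, and Aqp3, Tns4, Pinx1 and Atxn1 7 against 0 each. Pkp1 encodes the desmosome protein plakophilin 1, and Aqp3 the main water channel of the epidermis. On the day 0 side, Galnt16, Abca8b and Clmn had 7 against 0, and Vstm4, Dpt, Bmper, Eln and Lrrc32 6 against 0 each; Dpt and Eln encode the matrix proteins dermatopontin and elastin. Sfi1 (9 against 0) is uncertain as above, and Lrrc32 had 1 more region at day 7 with the lists as deposited. Pdgfra had 1 region only at day 7, 4 only at day 0 and 2 in both, Prrx1 had 1, 5 and 3, and Cd44 6, 0 and 7.

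**Figure D3:**
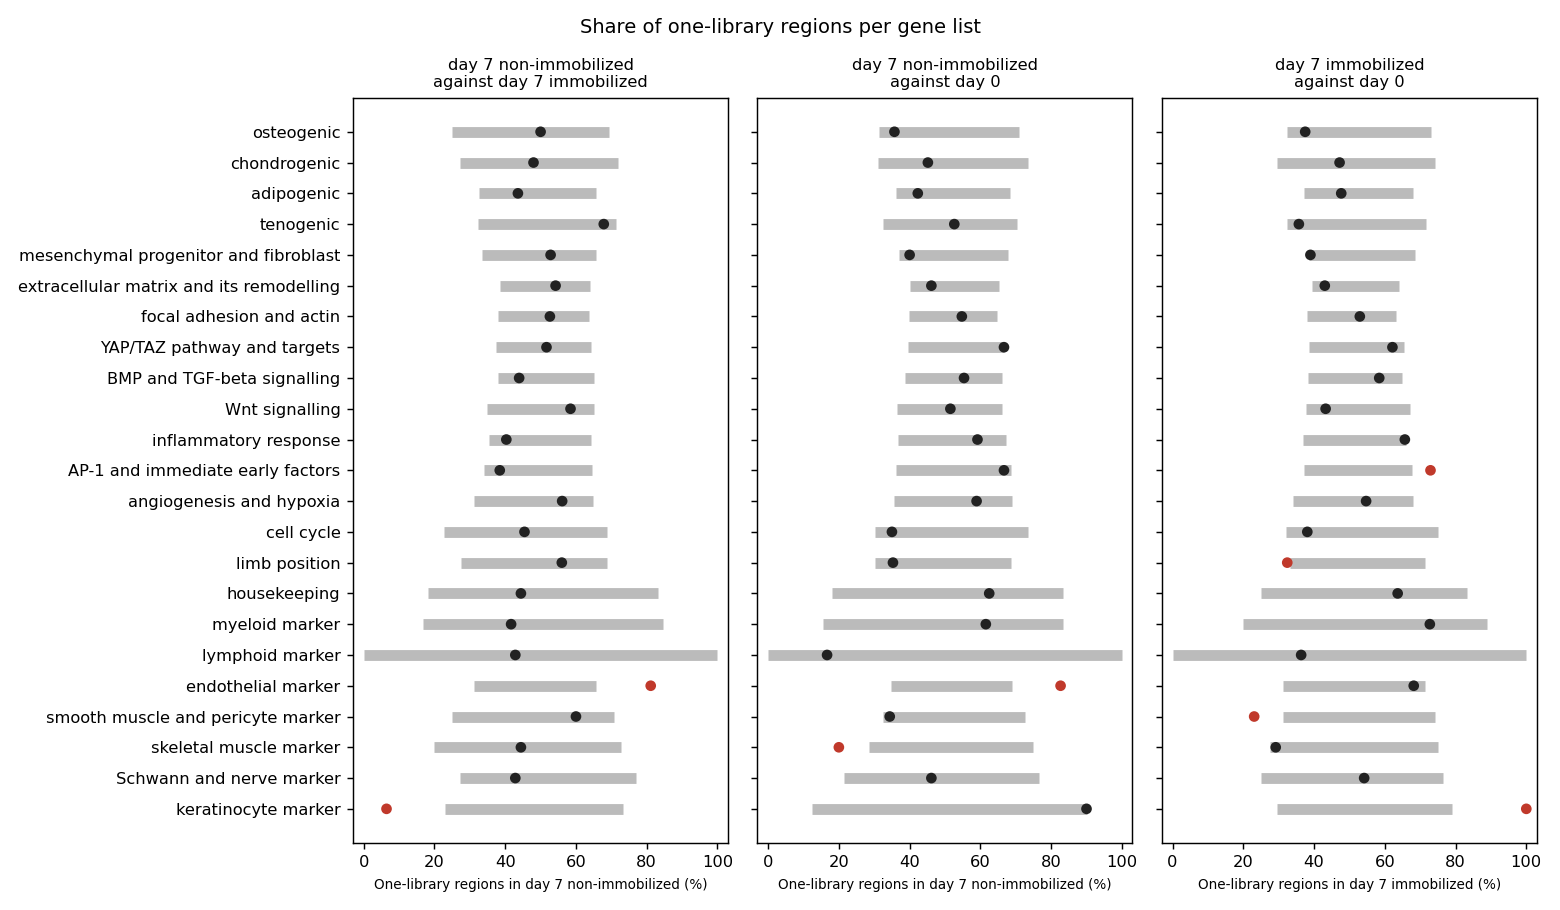
Each point is the percent of a gene list's one-library regions that were in the first library of the pair, for 23 lists in 3 pairs; grey bars span the middle 95% of 10000 random lists, and red points lie outside it. The endothelial list stands at 81.1% in the pair of day 7 libraries and 82.7% in non-immobilized against day 0, and the keratinocyte list at 6.45% in the pair of day 7 libraries and 100% in immobilized against day 0.

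Over the 3 pairs, 8 of the 69 list comparisons stood apart, where 3.45 would do so by chance. The comparisons are not independent, because the pairs share libraries, so the spread around 3.45 is not known. The endothelial list stood apart in both pairs with the non-immobilized library, and the keratinocyte list in both with the immobilized one. With the 23956 best summits of each list 3 stood apart, close to the 3.45 of chance, and with the lists as deposited 11 did. Among regions from the 23956 best summits of one list that were absent from the other's whole deposited list, 2 of 63 did. A chance number of 3.15 does not apply there, since some shares were at their limit and could not stand apart. The remaining settings gave 5 to 13. Regions called at day 7 and not at day 0 overlapped between the day 7 libraries. Of the 12687 such regions of the non-immobilized library, 5577 (44.0%, 43.1 to 44.8) were also called in the immobilized library. This share was 33.9% (highest 34.9%) when the library names were shuffled within each region. Independent sets drawn from all 67219 regions would give 20.2%. Of the 13157 regions called at day 0 and absent from the non-immobilized library, 9556 (72.6%, 71.9 to 73.4) were also absent from the immobilized one. Shuffling gave 66.2% (highest 67.4%), and independent sets drawn from all regions would give 19.4%. Neither value for independent sets is a chance level. Regions called at day 7 and not at day 0 can lie only outside the day 0 regions, and regions lost by day 7 only within them. Both comparisons use the single day 0 library, which could not be split, so part or all of either excess over shuffling may come from that shared library.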

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

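The tests that set one marker list against the other, and those on the mesenchymal list, were chosen after their results were seen. The second lists of epithelial and endothelial genes were written after the patterns were seen and before the second lists' results were. The rule that the percentile of a share at its limit decides nothing was adopted after the result it applies to. Percentiles with the lists as deposited and with the 23956 best summits of each list had been seen before any of these tests was written.

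Keratinocyte marker regions leaned to the immobilized library, with 6.45% of one-library regions in the non-immobilized one; the difference between groups of 1 library was not tested. Without Grhl3 the list stayed at percentile 0.21, which argues against a single locus. A lower share of mesenchymal cells that raised all other cell types alike was not seen, since the endothelial list stood at 99.99, on the other side. That does not bear on a lower mesenchymal share with only some other cell types raised. Epithelial cells in that preparation may be a source: a second list of 34 epithelial genes, with 0 held by the fixed lists, stood at percentile 0 (10 regions against 50), and 13 of the 14 keratinocyte markers had a region there, against 9 in the non-immobilized library and 8 at day 0; no sort is named in the labels. The score cutoff stays open: among regions from the 23956 best summits of one list, absent from the other's whole list, the percentile was 16.71, which met the prediction written beforehand for a cutoff effect, but all 5 regions were in 1 library and no lower percentile existed. With the 23956 best summits of each list the first list gave 9.11 and the second 0.065. A difference within the mesenchymal cells also stays open, since their own list gave 68.03 between the day 7 libraries. Against day 0 that list leaned to day 0 in both, at 2.735 for the immobilized and 5.28 for the non-immobilized library.

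Endothelial marker regions leaned to the non-immobilized library, with 81.13% of one-library regions there; this difference was not tested either. Without its leading member the list stayed at percentile 99.96. A lower share of mesenchymal cells that raised all other cell types alike was not seen here either, with the keratinocyte list at 0.04. Endothelial cells in that preparation may be a source, since a second list of 32 endothelial genes stood at 99.88 (51 regions against 19). In the equal-length lists the first list's markers had 90 regions there, 57 in the immobilized library and 41 at day 0. Those lists left out 19492 summits of the immobilized library. With the lists as deposited, more endothelial one-library regions lay in the immobilized library, though random lists leaned further that way. The number of first-list markers with a region did not differ between the equal-length day 7 lists: 17 in each, and 14 at day 0. No sort is named in the labels. The score cutoff stays open here too: the prediction for a cutoff effect was met at 95.23, on 2 regions that were both in 1 library, and the second list, with 2 regions on each side, did not stand apart under that setting (73.87), although it did with the 23956 best summits of each list (99.96, against 97.03 for the first). Endothelial cells cannot be told apart from a difference within mesenchymal cells, whose list gave 68.03.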

How the results depend on the processing

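The settings strict absence (regions from the 23956 best summits of one list, absent from the other's whole deposited list), assignment to the gene that holds the summit, lists without the member with the most one-library regions, and window widths for the share near a gene end were chosen after seeing the data. No paired analysis was possible because each group holds 1 library, and leaving out replicates does not apply. The motif alternatives were not run for lack of sequence. Depth can affect which weak summits are listed, although the library with the most estimated pairs had the shortest list, and this was not tested. Absence from a list is not absence of accessibility. Except where list length itself sets a count, the cause was not tested.

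Counts of one-library regions moved with list length by construction. With the lists as deposited, regions called in non-immobilized and not immobilized numbered 5609, the reverse 24484, and immobilized and not day 0 25065. With the 23956 best summits the counts were 4268 and 4392 between the day 7 libraries, 5348 and 5454 for non-immobilized and day 0, and 5319 and 5301 for immobilized and day 0. Under strict absence they were 558 and 1222, 2143 and 1463, and 2113 and 780. Requiring summits within 100 bp gave 16083 regions in non-immobilized and not immobilized.

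Of regions called in non-immobilized and not at day 0, the percent also called in immobilized was 64.78 with the lists as deposited, 39.87 with windows of 100 bp and 46.86 with 500 bp. The reverse was 30.04 as deposited and 44.56 with the best summits. Of day 0 regions absent from non-immobilized, the percent also absent from immobilized was 55.11 as deposited, 73.54 with the best summits and 71.39 with 500 bp windows. The reverse was 84.92, 75.66 and 74.36.

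The percent of regions near a gene end was higher for regions of all 3 libraries than for those of 1 library under each setting: 33.22 as deposited, 52.52 with the best summits, 31.05 within 500 bp and 40.4 within 2 kb. For non-immobilized alone it was 11.99, 15.31, 4.81 and 16.6. For immobilized alone it was 10.82 with the best summits, 4.287 within 500 bp and 11.57 within 2 kb, and for day 0 alone 8.402, 3.359 and 11.11. Windows of 100 bp gave 14.23 for non-immobilized, 9.751 for immobilized and 9.747 for day 0 alone, and windows of 500 bp 5.771, 5.667 and 4.204.

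Of the 8 lists that stood apart, all 8 did so with windows of 100 and 500 bp and with distal regions, 6 as deposited and 1 with the best summits (endothelial, non-immobilized and day 0). Under strict absence 1 still stood apart, 4 no longer did and 2 lay on the other side of 50. The 1 that held was the smooth muscle or the skeletal muscle list, whose strict absence values are not given here. Between the day 7 libraries the best summits gave percentile 97.03 for endothelial and 9.11 for keratinocyte markers, and strict absence 95.23 (2 regions and 0) and 16.71 (0 and 5). For non-immobilized and day 0, endothelial markers were at 91.55 under strict absence (19 and 0), and skeletal muscle at 29.42 with the best summits, 4.575 within 10 kb and 3.525 without the leading member. For immobilized and day 0, keratinocyte markers were at 95.64 with the best summits and 81.15 under strict absence (10 and 0), and smooth muscle at 6.395 with the best summits and 5.345 within 10 kb. The AP-1 list was at 89.49 as deposited, 90.12 with the best summits and 95.6 without its leading member, and on the other side of 50 within 10 kb (38.44) and under strict absence (47.42). The limb list was at 3.13 as deposited, 29.62 with the best summits, 3.655 within 10 kb, 4.505 within 100 kb, 16.71 by the gene that holds the summit and 4.855 without its leading member, and at 83.9 under strict absence, on 1 region. Apart from the AP-1 value, each strict absence value given here rests on regions of 1 library. No more extreme percentile existed, so the percentile decides nothing. That limit belongs to the percentile and not to the counts. In the largest case, the endothelial 19 and 0 stand beside 2143 and 1463 for all regions of non-immobilized and day 0. This difference was not tested. Of the lists that did not stand apart, 1 to 8 came to do so per setting.

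With the lists as deposited, the difference in regions changed sign for Lrrc32 (-2), Mgll (-4) and Chst15 (-1) between the day 7 libraries and for Lrrc32 (1) between immobilized and day 0. It was 0 for Sfi1 and C130026I21Rik between the day 7 libraries, and kept its sign for the other genes named by size under each setting run.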

Other observations

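Epithelial and endothelial genes outside the fixed lists were also counted against day 0. The second epithelial list had 68 regions called only in the immobilized day 7 library and 10 only at day 0 (percentile 100), and 29 and 11 for the non-immobilized library (97.8). The second endothelial list had 73 regions only in the non-immobilized library and 22 only at day 0 (percentile 99.99), and 37 and 18 for the immobilized library (96.0). Krt17, a keratin of stressed epidermis, had 3 regions, all in the immobilized library. Over the keratinocyte markers, 11 regions were called at day 0, 46 at day 7 immobilized and 19 at day 7 non-immobilized, and over the endothelial markers 41, 57 and 90. These counts are from the equal-length lists. The order of the endothelial counts of the day 7 libraries depended on list length.

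Myeloid markers had 18 regions at day 0, 23 at day 7 immobilized and 21 at day 7 non-immobilized, and lymphoid markers 12, 9 and 8. Genes with 5 or more one-library regions, all in 1 library, numbered 54 for non-immobilized and 26 for day 0 in that pair, and 57 for immobilized and 38 for day 0. In 1000 random allotments of single regions the means were 18.25, 11.93, 21.27 and 10.42, and the highest numbers 33, 22, 38 and 22.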
